A study of Mus musculus with 4 samples.

How the data were processed

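RNA sequencing was done on 4 libraries of lung fibroblasts freshly isolated from wild-type BALB/c mice aged 4 weeks. Per the labels, 2 libraries came from untreated control cells and 2 from cells given recombinant human CXCL1 at 8 nM, CXCL2 at 2 nM and CXCL8 at 20 nM for 3 hours. CXCL1, CXCL2 and CXCL8 are secreted chemokines that attract neutrophils through the receptors CXCR1 and CXCR2. Libraries are called control 1 and 2 and chemokine 1 and 2 after the replicate numbers in the labels. The labels do not say whether replicates were separate cultures or animals, so p-values of single genes measure only the spread between these samples, which may be technical.

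Per the submitters' processing notes, the authors used TopHat2 2.0.7, DESeq2 and the mouse build GRCm38/mm10, with no role or order given for the tools. The annotation release, the counter, the strand setting and the rule by which genes were kept are not given in the sources used here. The deposited table holds 2979 genes with 1 value per library, which the authors gave in RPKM, a read number scaled by gene length and library total. The header does not state this unit and it was worked out from the values. Every value in all 2979 genes equals a whole number of reads multiplied by 1000000000 and divided by a length fixed per gene and a whole-number total fixed per library, with a relative error of at most 1.3e-14. For 1176 genes the implied length equals the length of the union of exons in GENCODE M21, and only for these are the exact read numbers known. For the other genes the reads are the smallest whole numbers that fit the values, multiplied to bring the implied length nearest to the annotated length, and could not be checked. The deposited table also has 1 fold, a linear ratio of chemokine over control that the authors computed, which differs from the ratio of mean RPKM by at most 0.805% for any gene.

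The table is a list selected by the authors. In none of the 2979 genes do the values of the 2 groups overlap, no authors' fold lies between 0.906 and 1.12, and the higher of the group means is at least 1.01 RPKM. A test on such a list is not independent of the selection, and adjusted p-values over the listed genes do not stand for all genes measured. Genes outside the list were not analysed here, and nothing is said of whether they changed.

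The implied library totals were 31859688 reads for control 1, 36863654 for control 2, 28603764 for chemokine 1 and 33854493 for chemokine 2. Among the 1176 genes with exact reads, the median gene had between 1571 and 2270.5 reads per library and the lowest value was 24 reads. The chi-square between the libraries of a pair, per gene over the same 1176 genes, was 3.65 for control and 11.1 for chemokine, where sampling noise alone gives about 1, so neither pair was treated as 1 library deposited 2 times. This does not show whether the libraries came from separate cultures or animals. Precision is limited less by depth than by the 2 libraries per group.

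The planned test for counts was replaced by the one planned for normalized values. The test was limma's moderated test with a mean-variance trend on log2(RPKM + 1), over the 2956 listed genes with a mean of at least 1 RPKM over the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes come from this test, all tests are two-sided, and log2 fold changes are on the log2(RPKM + 1) scale with their SE, which understates the change of low genes. An exact permutation of 2 against 2 libraries has 3 distinct splits and cannot give a p below 0.333. Named genes were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls past the threshold, up to 4 members of each gene list by size of change, and Cxcr2, Cxcr1, Ackr1, Cxcl1, Cxcl2 and Cxcl5 wherever measured. Of the genes it takes, 106 are named and 2 are not reported here. Others are said to be chosen after their values were seen.

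The 19 gene lists and 9 lists of cell type markers were also fixed before the data were examined. Lists with at least 5 tested members were compared with the other listed genes by limma's camera with a preset correlation of 0.01, adjusted over the 14 such lists, and for markers over the only such list. With the correlation estimated from the data, none of the 14 lists passed, and the lowest unadjusted p was 0.143. In all 28 lists the numbers that rose and fell were equal when adjusted over the list alone and when adjusted over all tested genes. This could not have come out otherwise, since all 2956 tested genes had an unadjusted p under 0.05 by limma. Of these lists, 2 had no listed member. Gene positions, exon lengths and GC content come from GENCODE M21 on GRCm38, in which 2976 of the 2979 identifiers were found. Reads of overlapping antisense genes cannot be told apart without the strand setting. Those of same-strand overlaps and near-identical copies cannot be told apart by that setting alone. Of the 106 named genes, 40 share exon bases with another annotated gene.

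After the data were seen, each list was also set against 10000 random lists of listed genes matched on 10 classes of exon length and, within each, 3 classes of GC content, with the median of log2 fold as the statistic. The smallest p this gives is 0.0002. The random lists come from genes selected as changed, so a list near them resembles other selected genes, whatever the cause. The draws treat genes as independent and do not measure the spread between libraries. The fold in this comparison is the ratio of geometric means, and p-values were adjusted over 23 lists. Correlations with length are across genes, which are not independent replicates. Their 95% intervals come from 1000 bootstrap draws of genes.

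Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 10 RPKM, limma without trend, voom on the recovered or inferred reads of all 2956 tested genes, a tested minimum fold of 1.2, a replicate block, leaving out each library, an estimated correlation for lists, and a minimum of 5 RPKM for the spread between libraries. Planned scalings, filters and tests that need a table of raw counts were not run. Added after the data were seen were the scaling implied by the authors' fold, adjustment over all 55450 annotated genes with those outside the table given a p of 1, a test with no variance moderation, a crossed pairing, and removal of each library's trend with length and GC. That trend was fitted over the listed genes alone. A value of 0 after its removal therefore means a change like that of listed genes of the same length and GC, not no change.

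The recovery of reads, the limma test and the matched comparison were tested on simulated data, and the other steps were not. For 100% of 400 simulated genes whole reads were recovered up to a factor common to the libraries. The choice of that factor from the annotated length was not simulated. In 4 simulated libraries of 2979 genes, the limma test of chemokine against control called 8% of 50 genes changed by a fold of 1.1, 76% at 1.3, 94% at 1.5 and 98% at 2, and 10 of its 148 calls were false. This simulation held no length trend and no selection of changed genes, so its rates do not describe the test on the selected list. The matched comparison called 2% of simulated lists of 20 genes with no shift and 98% of those shifted by 0.15 on the log2 scale. Its simulated genes were independent and not selected as changed. Lists as small as 3 or 4 genes were not simulated, so these rates do not describe them. The work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.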

Results

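Gene expression was measured by RNA sequencing in lung fibroblasts, the matrix-producing cells of connective tissue, freshly isolated from mice and either left untreated (n = 2 libraries) or exposed for 3 hours to recombinant human CXCL1, CXCL2 and CXCL8 (n = 2 libraries). The series asks how these chemokines affect lung fibroblasts. The implied depth was 31859688 and 36863654 reads in the control libraries and 28603764 and 33854493 reads in the chemokine libraries. The values cover 2979 genes that the authors had already selected as different between the groups.

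Most changes were small, and more of the listed genes were lower than higher after chemokine exposure, though not among those with higher expression. A fold above 1 was given for 1264 genes (42.4%) in the authors' deposited table, with a median of 1.26, and a fold below 1 for 1715 genes (57.6%), with a median of 0.768. Only 31 genes of that table reached a fold of 1.5, and 253 fell to 1/1.5 or below. Of the 2956 genes tested, 1264 rose and 1692 fell at an adjusted p under 0.05 by limma, which is every gene tested, as the selection of the list makes nearly certain. The numbers dropped to 97 and 310 when a fold of at least 1.2 was required in the same test. At a mean of at least 10 RPKM the balance turned round, with 1098 rises and 691 falls.

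Mgp, which encodes matrix Gla protein, an inhibitor of tissue calcification, rose from 54.5 ± 0.794 to 92.5 ± 0.542 RPKM (SD, n = 2 per group). Saa3, an acute phase serum amyloid, rose from 125 ± 5.77 to 207.6 ± 8.41 RPKM (SD, n = 2 per group). Mt2, a metallothionein that binds zinc and copper, rose from 229 ± 2.33 to 352 ± 40.5 RPKM (SD, n = 2 per group). Limma's log2 fold changes were 0.75 ± 0.04 for Mgp, 0.73 ± 0.05 for Saa3 and 0.61 ± 0.07 for Mt2 (SE), with adjusted p of 0.000118, 0.000118 and 0.000232. Sox18, a transcription factor of vascular endothelium, had the largest log2 fold change upward, 0.82 ± 0.07 (SE), from 76 and 96 reads in the control libraries to 149 and 205 in the chemokine libraries. Cda, cytidine deaminase, had the highest fold of the authors' deposited table, 2.35, on 24 and 34 control reads and 55 and 68 chemokine reads. The other largest rises were in Ear2, an eosinophil-associated ribonuclease, with a log2 fold change of 0.66, Scand1 (0.76), Polr2f (0.60), Gm13889 (0.66), Gm20481 (0.63) and the processed pseudogenes Gm17511 (0.78) and Gm7367 (0.73). Scand1, Polr2f, Gm13889, Gm20481 and Mt2 share exon bases with another annotated gene, for Gm20481 the heat shock gene Hspa1a, and pseudogenes can share reads with their parent genes, so these values are uncertain.

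Inhba, the subunit of the growth factor activin A, fell from 341 ± 25.5 to 146 ± 27.4 RPKM (SD, n = 2 per group), a log2 fold change of -1.23 ± 0.11 (SE). Tnfsf15, a cytokine of the tumour necrosis factor family, fell from 20.5 ± 0.381 to 9.52 ± 1.31 RPKM (SD, n = 2 per group). Cbl, a ubiquitin ligase that turns off receptor tyrosine kinases, fell from 5.31 ± 0.0887 to 2.03 ± 0.299 RPKM (SD, n = 2 per group). Arid5b, a DNA-binding regulator of adipocyte genes, had a log2 fold change of -1.01 ± 0.09 (SE). Limma's adjusted p was 0.000144 for Inhba, 0.000137 for Tnfsf15, 0.000118 for Cbl and 0.000142 for Arid5b. The largest fall was that of Gm26992, -1.69 ± 0.13 (SE), on 135 and 138 control reads and 33 and 24 chemokine reads. This gene spans bases 103422010 to 103481705 of chromosome X and shares exon bases with Tsx, Tsix and Xist, so its reads are uncertain. Zbed6 (-1.33) lies inside Zc3h11a and shares its exon bases. Gm21897, Gm21962, Gm21750 and Gm21833, with log2 fold changes from -1.03 to -0.98, share from 24% to 44% of their 31-base words pairwise. Gm9869, with a fold of 0.451 in the authors' deposited table, lies inside Uaca.

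The listed members of the axis that was stimulated were higher in the chemokine libraries, less so once the trend with gene length was removed. Cxcr2, the receptor for the added chemokines, rose from 6.18 ± 0.144 to 8.63 ± 0.868 RPKM (SD, n = 2 per group), a log2 fold change of 0.42 ± 0.07 (SE) with an adjusted p of 0.000576 by limma. It is also the only one of 15 chemokine receptors on the fixed list that the table holds, and Cxcr1 and Ackr1 were not analysed here. Mouse Cxcl1, itself a ligand of Cxcr2, rose from 67.9 ± 2.66 to 95.7 ± 3.23 RPKM and Cxcl2 from 8.69 ± 0.102 to 11.4 ± 0.057 RPKM (SD, n = 2 per group). Of 7 genes fixed as a list of CXC chemokines with the ELR motif, 4 were tested and rose, with log2 fold changes of 0.49 ± 0.05 for Cxcl1, 0.36 ± 0.05 for Cxcl2, 0.28 ± 0.07 for Pf4 and 0.27 ± 0.05 for Cxcl5 (SE). Pf4, platelet factor 4, is a CXC chemokine that lacks this motif, so the list is wider than its name. With the trend of length and GC removed, Cxcl1 (0.19 ± 0.06) and Cxcr2 (0.28 ± 0.05) still passed, Cxcl2 did not (0.08 ± 0.04, limma adjusted p = 0.185), and Cxcl5 (-0.02 ± 0.04) and Pf4 (-0.04 ± 0.05) turned without passing. Among 23 other chemokines 3 were tested and all rose. They were the monocyte attractants Ccl2, from 251 ± 14.3 to 369.6 ± 21.2 RPKM, and Ccl7, from 102 ± 1.96 to 147 ± 17.5 RPKM, and the membrane-bound Cxcl16, with a log2 fold change of 0.30 ± 0.06 (SE). Limma's adjusted p was 0.000189 for Cxcl1 and Ccl2, 0.00033 for Cxcl2 and 0.000412 for Ccl7. Ccl2, Ccl7 and Cxcl16 passed under the same removal, at 0.20 ± 0.04, 0.18 ± 0.05 and 0.16 ± 0.05. The ELR list with Pf4 had a median fold of 1.27, against 1.24 in listed genes of the same length and GC classes (p = 0.713, permutation of lists). The other chemokines had a median fold of 1.43 against 1.25 (permutation of lists, p = 0.012, adjusted p = 0.129).

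**Figure D1:**
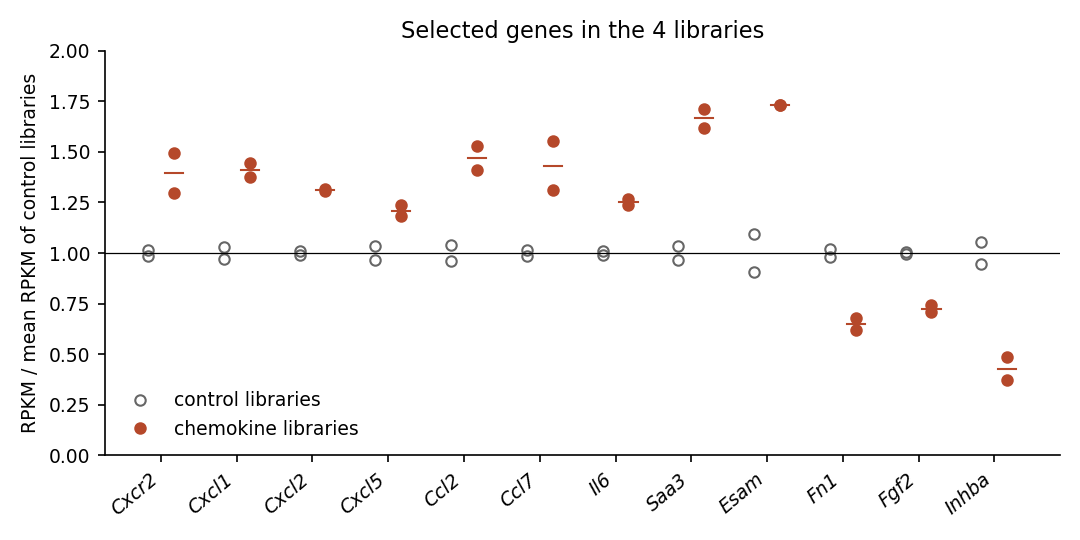
RPKM of 12 genes in each of the 4 libraries, divided by the mean of the control libraries of the same gene. Open circles are control libraries, filled circles chemokine libraries and short lines the means of the 2 chemokine libraries. In all 12 genes, as in all 2979 listed genes, both chemokine libraries lie on the same side of both control libraries. They lie above for 9 genes and below for Fn1, Fgf2 and Inhba.

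In the reference build GRCm38, Cxcr2 (ENSMUSG00000026180) lies on chromosome 1 from 74153989 to 74161246 on the plus strand. Cxcl1 (ENSMUSG00000029380) and Cxcl2 (ENSMUSG00000058427) are neighbours on chromosome 5, from 90891241 to 90893115 and from 90903871 to 90905938, both on the plus strand. Ccl2 (ENSMUSG00000035385) and Ccl7 (ENSMUSG00000035373) are likewise neighbours on chromosome 11, from 82035571 to 82037453 and from 82045712 to 82047525. Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46711998 to 46715700 on the minus strand, and Inhba (ENSMUSG00000041324) on chromosome 13 from 16011851 to 16031621 on the plus strand. All are protein-coding, and for Cxcr2 and Ccl7 the implied length equals that of all annotated exons together, while for the other 5 it does not. Cxcr2 had 610 and 683 reads in the control libraries and 699 and 954 in the chemokine libraries, and Ccl7 had 2580 and 3067 against 3078 and 4314.

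Inflammatory genes outside the chemokine families moved both ways. Of 40 targets of NF-kB and inflammatory cytokines, 9 were tested, 6 rose and 3 fell. Those that rose included Il6, a cytokine that drives the acute phase response, with a log2 fold change of 0.32 ± 0.04 (SE) from 164 ± 2.44 to 205 ± 3.57 RPKM (SD, n = 2 per group). Ier3, an early response gene, rose by 0.41 ± 0.05 and Nfkbib, an inhibitor of NF-kB, by 0.33 ± 0.07, while Rel, a subunit of NF-kB itself, fell by 0.31 on the log2 scale (SE 0.05). Under removal of the length and GC trend Il6 passed (0.13 ± 0.03), while Ier3 (0.03 ± 0.03), Nfkbib (0.02 ± 0.06) and Rel (-0.04 ± 0.04) did not. As a whole this list did not pass against the other listed genes (camera, adjusted p = 0.208). All 5 tested of 26 acute phase, complement and immunoregulatory genes rose, among them Serping1, the C1 inhibitor (0.42 ± 0.07), Ptx3, a pentraxin (0.38 ± 0.09), and Lgals1, galectin 1 (0.27 ± 0.05). The list was higher than the other listed genes by camera (adjusted p = 0.0379), but not with an estimated correlation (adjusted p = 0.512) or with the length and GC trend removed (adjusted p = 0.437), and its adjusted p ranged from 0.0194 to 0.512 over the alternatives in which it was tested, which leave out the filter at a mean of 10 RPKM. Its median fold of 1.35 compared with 1.25 in length- and GC-matched genes (permutation of lists, p = 0.0462, adjusted p = 0.212). Of 40 interferon-stimulated genes only 3 were tested. B2m, of the MHC class I complex, rose (0.30 ± 0.05), while Trim25 and Eif2ak2, both of antiviral RNA sensing, fell (-0.35 ± 0.06 and -0.29 ± 0.05). Trim25 and Eif2ak2 passed with the trend removed, whereas B2m turned to -0.03 ± 0.04 without passing. Of the acute phase genes Saa3 passed (0.53 ± 0.04), Serping1 (0.17 ± 0.06) and Ptx3 (0.19 ± 0.08) did not, and Lgals1 turned to -0.105 ± 0.04 without passing.

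Immediate early genes, which respond within minutes to growth factors, were split. Of 14 tested of 38, 8 rose and 6 fell. Jund and Junb, subunits of AP-1, rose with log2 fold changes of 0.52 ± 0.05 and 0.37 ± 0.07 (SE). Fosl2, another AP-1 subunit, and Dusp4, a phosphatase that inactivates MAP kinases, fell, with log2 fold changes of -0.35 ± 0.06 and -0.48 ± 0.06 (SE). Only Dusp4 of these 4 passed with the length and GC trend removed, with Jund at 0.11 ± 0.04, Junb at 0.05 ± 0.06 and Fosl2 at -0.04 ± 0.04. The list did not pass against the other listed genes (camera, adjusted p = 0.45), and across its 14 members fold fell with exon length (Spearman's rho -0.741, permutation p = 0.0037, adjusted p = 0.0148). Its median fold of 1.14 compared with 1.21 in matched genes (permutation of lists, p = 0.0168, adjusted p = 0.129).

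Matrix genes moved both ways. Of 20 tested extracellular matrix genes among 40, 8 rose and 12 fell. Fibrillar collagens were among those that rose, Col3a1 from 47.8 ± 0.291 to 62.9 ± 0.186 RPKM and Col1a1 from 474 ± 3.35 to 554 ± 19.6 RPKM (SD, n = 2 per group), while the adhesive glycoprotein fibronectin, Fn1, fell from 293 ± 7.71 to 190.4 ± 12.7 RPKM. Col12a1, a fibril-associated collagen, and the basement membrane genes Nid1 and Lama4 also fell, with log2 fold changes of -0.61 ± 0.06, -0.51 ± 0.05 and -0.48 ± 0.05 (SE). The number of matrix genes that rose was 5 without control 2. Matrix proteases and their inhibitors had 8 tested of 30, of which 5 rose and 3 fell. Ctsk, the collagen-degrading cathepsin K, rose by 0.41 ± 0.05 and Timp1, an inhibitor of metalloproteinases, by 0.32 ± 0.05, while Timp3 and Adam12 had log2 fold changes of -0.44 ± 0.05 and -0.44 ± 0.05 (SE). Neither list passed against the other listed genes by camera (adjusted p = 0.563 and 0.413). Fold fell with exon length across the members of both, with a Spearman's rho of -0.584 for matrix genes (permutation p = 0.0099, adjusted p = 0.0297) and -0.952 for proteases and inhibitors (permutation p = 0.0015, adjusted p = 0.009). Col3a1, Col1a1, Fn1, Col12a1, Nid1 and Timp3 passed in the same direction with the length and GC trend removed. Lama4 (-0.12 ± 0.04), Adam12 (-0.09 ± 0.03) and Ctsk (0.07 ± 0.04) did not pass, and Timp1 turned to -0.04 ± 0.05 without passing.

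Contractile genes also moved both ways. Of 14 tested of 30, 6 rose and 8 fell. The actin-binding proteins Flna, Cald1 and Actn1 had log2 fold changes of -0.42 ± 0.06, -0.40 ± 0.05 and -0.37 ± 0.05 (SE), while Tpm2, a tropomyosin, rose by 0.32 ± 0.04. Acta2, the smooth muscle actin that marks myofibroblasts, changed from 2471 ± 45.3 to 2784 ± 39.3 RPKM (SD, n = 2 per group), a log2 fold change of 0.17 ± 0.05 (SE). Its limma adjusted p of 0.00627 became 0.0552 without control 1 and 0.12 without control 2. The number of contractile genes that rose was 3 without control 1. The list did not pass against the other listed genes (camera, adjusted p = 0.995), and across its 14 members fold fell with exon length (Spearman's rho -0.793, permutation p = 0.0009, adjusted p = 0.009). Flna (-0.12 ± 0.04), Actn1 (-0.23 ± 0.04) and Tpm2 (0.14 ± 0.04) passed with the length and GC trend removed, Cald1 did not (-0.04 ± 0.03), and Acta2 turned to -0.09 ± 0.04 without passing.

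Secreted growth factors were mostly lower. Of 7 tested of 32, 6 fell and 1 rose. Besides Inhba, Fgf2 fell from 130.6 ± 0.928 to 94.7 ± 3.14 RPKM and Fgf10, which drives branching of the lung epithelium, from 17.3 ± 0.634 to 14 ± 0.177 RPKM (SD, n = 2 per group). Inhba, Fgf2 and Fgf10 also passed with the length and GC trend removed. The list was not lower than the other listed genes by camera (adjusted p = 0.208), and its median fold of 0.81 compared with 0.83 in length- and GC-matched genes (permutation of lists, p = 0.692).

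Most listed stress genes were higher. All 6 tested of 20 heat shock genes rose, among them Hspa1a and Hspa1b, the inducible HSP70 genes, with log2 fold changes of 0.44 ± 0.05 and 0.35 ± 0.05 (SE), Hspb1 with 0.37 ± 0.05 and Hspe1 with 0.31 ± 0.06. The heat shock list was higher than the other listed genes (camera, adjusted p = 0.0348), but not with an estimated correlation (adjusted p = 0.512), without control 1 (adjusted p = 0.0505), among genes with a mean of at least 10 RPKM (adjusted p = 0.15) or with the length and GC trend removed (adjusted p = 0.521). Over all alternatives its adjusted p ranged from 0.029 to 0.521. Its median fold was 1.27, against 1.24 in matched genes (permutation of lists, p = 0.489). Hspa1a and Hspa1b passed with the length and GC trend removed (0.24 ± 0.04 and 0.13 ± 0.04), while Hspb1 (-0.04 ± 0.05) and Hspe1 (-0.03 ± 0.05) turned without passing. Of 9 tested genes of the unfolded protein and integrated stress response among 30, 7 rose and 2 fell. Trib3, Ddit3, Manf and Atf4 rose, by 0.33 ± 0.06, 0.31 ± 0.07, 0.30 ± 0.05 and 0.27 ± 0.05 on the log2 scale (SE), and the list did not pass (camera, adjusted p = 0.105). Of these 4 only Manf passed with the trend removed (0.22 ± 0.04), with Trib3 at 0.02 ± 0.05, Atf4 at 0.00 ± 0.04 and Ddit3 at -0.01 ± 0.09. The median fold of this list was 1.2, against 1.21 in matched genes (permutation of lists, p = 0.666). The number that fell was 1 without control 1 and likewise without control 2. All 5 tested of 30 hypoxia and glycolysis genes rose, with Ankrd37, Higd1a and Slc2a1 at 0.41 ± 0.06, 0.36 ± 0.05 and 0.20 ± 0.05, although the list did not pass (camera, adjusted p = 0.0606). Without control 2, 3 of these 5 remained past the threshold, and Ldha was among those lost (adjusted p = 0.0606 by limma). All 3 tested of 25 genes of cholesterol synthesis rose, Mvk by 0.39 ± 0.06, Ebp by 0.33 ± 0.05 and Fdps by 0.24 ± 0.05. Higd1a, Mvk and Fdps passed with the trend removed, while Ankrd37, Slc2a1, Ldha and Ebp did not. The median fold was 1.15 for the hypoxia list and 1.29 for cholesterol synthesis, against 1.23 and 1.22 in matched genes (permutation of lists, p = 0.0858 and 0.308).

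Of 11 tested p53 targets and senescence genes among 28, 7 rose and 4 fell (camera, adjusted p = 0.208). Gadd45a and Ddit4, both induced by stress, rose by 0.46 ± 0.05 and 0.45 ± 0.06 on the log2 scale (SE), Igfbp7, a secreted binding protein for insulin-like growth factors, by 0.47 ± 0.05 and Bax, which promotes apoptosis, by 0.37 ± 0.04. Gadd45a alone of these 4 passed with the length and GC trend removed (0.15 ± 0.04), with Igfbp7 at 0.07 ± 0.04, Ddit4 at 0.09 ± 0.07 and Bax at -0.03 ± 0.04. Of 7 tested cell cycle genes among 35, 4 rose and 3 fell (camera, adjusted p = 0.556). Mki67, the gene of the proliferation antigen Ki-67, fell from 15.2 ± 0.174 to 10.6 ± 0.468 RPKM (SD, n = 2 per group), while the mitotic genes Birc5, Ube2c and Ccnb2 rose by 0.37 ± 0.07, 0.32 ± 0.08 and 0.30 ± 0.05 on the log2 scale (SE). Mki67 (-0.15 ± 0.04) and Birc5 (0.29 ± 0.05) passed with the trend removed, Ube2c did not (0.09 ± 0.08), and Ccnb2 turned to -0.03 ± 0.04 without passing.

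Ribosomal protein genes and mitochondrially encoded genes were fixed as lists that can show differences in RNA quality between libraries, and most tested members were higher in the chemokine libraries. All 42 cytosolic ribosomal protein genes on the fixed list were in the table and all 42 rose, with Rplp1, Rplp2, Rpl13 and Rps18 at log2 fold changes of 0.48 ± 0.06, 0.45 ± 0.04, 0.44 ± 0.05 and 0.44 ± 0.06 (SE). Rplp1 went from 1451 ± 8.63 to 2025 ± 145 RPKM (SD, n = 2 per group). The list was higher than the other listed genes by camera (adjusted p = 1.75e-10), but not with an estimated correlation (adjusted p = 0.512), the highest value over all alternatives. With the length and GC trend removed it still passed (camera, adjusted p = 0.036), alone among the 14 lists. Its median fold was 1.27, against 1.25 in length- and GC-matched genes (permutation of lists, p = 0.0658, adjusted p = 0.252). Of the 13 mitochondrially encoded genes, 5 were tested, 4 rose and 1 fell. mt-Co2 and mt-Nd3 had log2 fold changes of 0.37 ± 0.07 and 0.28 ± 0.06 (SE), and mt-Nd5 of -0.20 ± 0.05. This list did not pass against the other listed genes (camera, adjusted p = 0.208), and its median fold of 1.16 lay below the 1.25 of matched genes (permutation of lists, p = 0.026, adjusted p = 0.15). Without control 2, 2 of the 4 rises remained past the threshold, and mt-Co3 was among those lost (adjusted p = 0.114 by limma). Without control 1 mt-Nd5 did not pass (adjusted p = 0.0519 by limma). The 4 named ribosomal protein genes, mt-Nd3 and mt-Nd5 passed in the same direction with the length and GC trend removed, mt-Co2 did not (0.09 ± 0.05), and mt-Co3 turned to -0.07 ± 0.05 without passing.

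**Figure D2:**
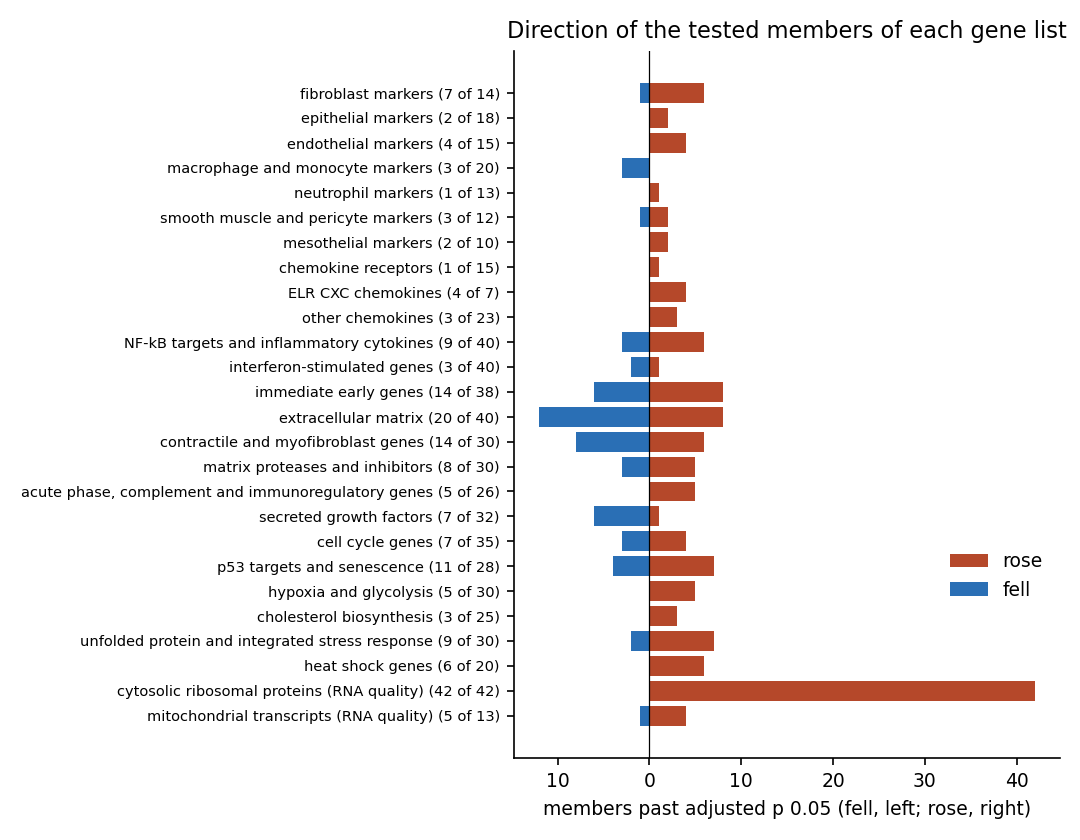
Number of tested members of each fixed gene list that rose (bars to the right) or fell (bars to the left) at an adjusted p under 0.05 in the chemokine libraries. Figures in brackets give the tested members and the size of the list. The 42 ribosomal protein genes all rose, and secreted growth factors had 6 falls and 1 rise. The list of ELR chemokines includes Pf4, which lacks the motif.

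Markers of other cell types were also among the listed genes. All 4 tested of 15 endothelial markers rose, Esam from 1.88 ± 0.251 RPKM in control to 3.26 RPKM in both chemokine libraries (n = 2 per group), and Egfl7, Ramp2 and Pecam1 by 0.45 ± 0.05, 0.36 ± 0.06 and 0.31 ± 0.06 on the log2 scale (SE). Their median fold of 1.42 exceeded the 1.15 of length- and GC-matched genes (permutation of lists, p = 0.0004, adjusted p = 0.0092). Egfl7 shares exon bases with Agpat2 among others and Ramp2 with Vps25, so the values of these markers are uncertain. All 3 tested of 20 macrophage and monocyte markers fell, Itgam by 0.46, Mrc1 by 0.33 and Laptm5 by 0.32 on the log2 scale (SE 0.06, 0.05 and 0.05). Their median fold was 0.779, against 0.837 in matched genes (permutation of lists, p = 0.329). All 4 endothelial markers, Itgam and Laptm5 passed with the length and GC trend removed, and Mrc1 did not (-0.11 ± 0.04, limma adjusted p = 0.052). The epithelial keratins Krt18 and Krt19, which are also on the mesothelial list, rose by 0.42 ± 0.05 and 0.36 ± 0.05. Neither passed with the trend removed (0.04 ± 0.04 and 0.02 ± 0.04). The surfactant gene Sftpb, the other listed epithelial marker, was below the expression filter and was chosen after its value was seen. Its fold in the authors' deposited table was 0.297. Among 12 smooth muscle and pericyte markers 3 were tested. Cnn1 and Acta2 were higher and Myh11 lower (-0.34 ± 0.07), but neither rise passed without control 1 (limma, adjusted p = 0.0827 for Cnn1 and 0.0552 for Acta2). With the trend removed Myh11 did not pass (-0.08 ± 0.05) and Cnn1 turned to -0.0016 ± 0.04 without passing. Cxcr2 was the only one of 13 neutrophil markers in the table, and no lymphocyte or erythroid marker of the 17 and 10 fixed was in it.

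Of 14 fibroblast markers 7 were tested, 6 rose and 1 fell. S100a4 rose by 0.33 ± 0.05 on the log2 scale (SE) and Npnt, nephronectin, fell by 0.37 (SE 0.04). With the trend removed Npnt passed and S100a4 did not (0.05 ± 0.04). The list was higher than the other listed genes (camera, adjusted p = 0.0422), but not with an estimated correlation (adjusted p = 0.172) and not without control 1, control 2 or chemokine 1 (adjusted p = 0.0999, 0.108 and 0.0514). Its adjusted p ranged over all alternatives from 0.00419, with the length and GC trend removed, to 0.274, at a mean of at least 10 RPKM. Its median fold of 1.135 compared with 0.811 in length- and GC-matched genes (permutation of lists, p = 0.0992, adjusted p = 0.285). Col1a1 and Col3a1, which are also among the collagens compared below, were among its rises. The number of fibroblast markers that rose was 3 without control 2.

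Across the listed genes, the direction of change followed the length of the gene. Exon length had a median of 2310 bases in genes above 1 and 8346 bases in genes below 1 in the authors' deposited table. When the genes were split by length into 10 classes of nearly equal size, 97% of the shortest class and 1.68% of the longest had a fold above 1. Spearman's rho between log2 fold and exon length across 2976 genes was -0.729 (95% interval -0.747 to -0.708), and genes are not independent replicates. The log2 fold changed by -0.23 per doubling of length. With this trend and that of GC content removed from each library, 582 genes rose and 594 fell of 2953 tested by limma. Of these calls, 110 had the opposite sign to before. The trend was fitted over the selected genes alone, so these are changes against listed genes of like length and GC. Such a fit tends to give a nearly even split, and a turned sign does not mean that the gene itself changed the other way.

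**Figure D3:**
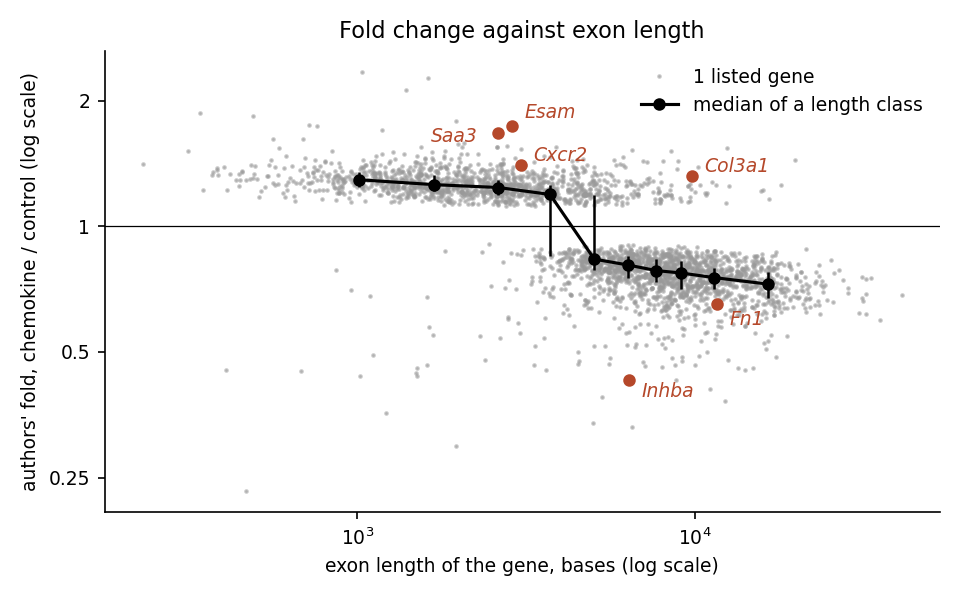
Fold of chemokine over control in the authors' deposited table against exon length, both on log scales. Each grey point is 1 gene, black points are medians of 10 classes of genes by length and black vertical lines run from the lower to the upper quartile. The median fold falls from 1.29 in the shortest class to 0.727 in the longest, while Esam, Saa3 and Col3a1 lie above the median of their class.

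The chemokine libraries differed more from each other than the control libraries did. The SD over listed genes of the log2 ratio of replicate 2 to replicate 1 was 0.13 for chemokine and 0.07 for control, and Pearson's r of log2 RPKM across genes was 0.9986 and 0.9993. Chemokine 2 lay farther from the controls than chemokine 1. Of genes that rose, 74.9% were higher in chemokine 2 than in chemokine 1, and of genes that fell, 82.4% were lower in it. The log2 ratio of chemokine 2 to chemokine 1 itself fell with exon length, with a Spearman rho of -0.513 (95% interval -0.54 to -0.483), where that of control 2 to control 1 had a rho of 0.137 (95% interval 0.1 to 0.171). Without chemokine 2, 1263 genes rose and 1692 fell.

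**Figure D4:**
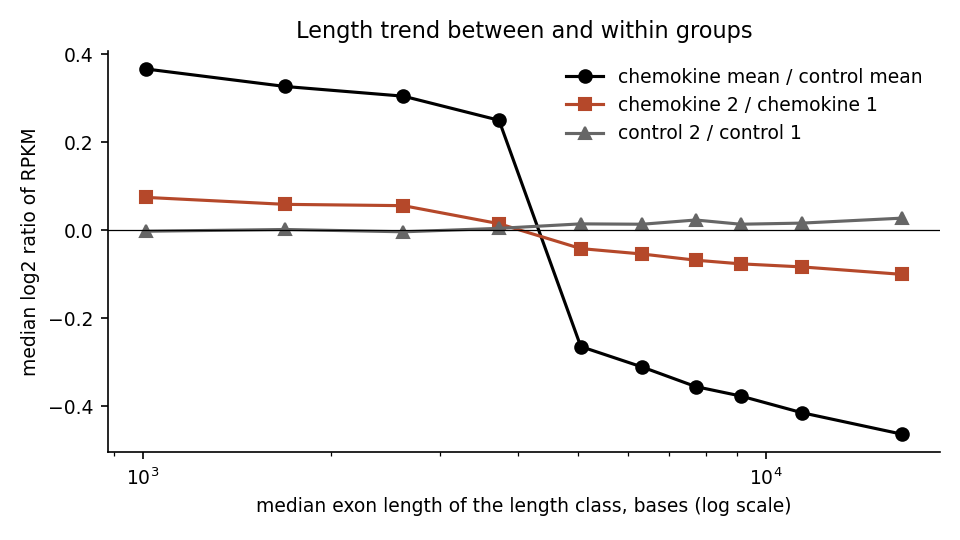
Median log2 ratio of RPKM in each of 10 classes of the listed genes by exon length, plotted at the median length of the class on a log scale. Circles are the means of the chemokine libraries over the control libraries, squares chemokine 2 over chemokine 1 and triangles control 2 over control 1. From the shortest to the longest class the ratio runs from 0.37 to -0.46 between groups, from 0.07 to -0.10 within the chemokine pair and from 0.00 to 0.03 within the control pair.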

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

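The counts, lists and named genes below refer to the listed genes only, and the alternatives chosen after seeing the data are named as such. The 1264 rises and 1692 falls by limma, which the selection of the list makes nearly certain, were within 1.5 times under most alternatives, and leaving out single libraries gave from 1189 to 1264 rises and from 1588 to 1692 falls. They moved to 97 rises and 310 falls with a minimum fold of 1.2, to 691 falls at a mean of at least 10 RPKM, where fewer genes were tested and the 1098 rises outnumbered them, and, chosen after seeing the data, to 669 rises with no variance moderation and to 582 rises and 594 falls with the trend of length and GC removed. With a replicate block 1264 genes rose and 1692 fell, and the correlation of same-numbered libraries' deviations was -0.154, from only 2 pairs, so the numbers do not establish a pairing. The crossed pairing, added after seeing the data, also gave 1264 rises and 1692 falls. Camera called 3 lists higher and none lower. It called 1 list at a mean of at least 10 RPKM, 0 with an estimated correlation, 1 with the length and GC trend removed, the ribosomal proteins, and from 2 to 3 without single libraries. The fibroblast markers' adjusted p of 0.0422 became 0.274 at a mean of at least 10 RPKM, 0.102 with the replicate block, 0.172 with an estimated correlation, 0.0749 under the scaling implied by the authors' fold, 0.00419 with the length and GC trend removed, and from 0.045 to 0.108 without single libraries. Apart from fewer genes or samples in the fit, the cause was not tested. The groups overlap in none of the listed genes, so the selection makes a kept direction nearly certain where only filter, scaling, test or libraries change. All 106 named genes kept their direction under every alternative in which they were tested but removal of the length and GC trend, and 74 of them were tested at a mean of at least 10 RPKM. Under that removal 93 kept it and 65 also passed the threshold, and 13 turned, none past it. Their log2 fold changes then were -0.0016 for Cnn1, -0.0853 for Acta2, -0.0373 for Pf4, -0.0154 for Cxcl5, -0.027 for B2m, -0.038 for Timp1, -0.105 for Lgals1, -0.0304 for Ccnb2, -0.0308 for Bax, -0.0071 for Ddit3, -0.0427 for Hspb1, -0.0264 for Hspe1 and -0.0739 for mt-Co3. Of the named genes, 59 did not pass with a minimum fold of 1.2, 30 with no variance moderation, 7 when adjusted over all annotated genes, and 3 each without control 1 and control 2. The SD of the log2 ratio of replicates was 0.07 for control and 0.12 for chemokine at a mean of at least 5 RPKM. Where leaving out a library left 1 sample in a group, that sample was assumed to vary like those of the other group. Planned scalings, filters and tests for raw counts were not run. Of the named genes with exact reads, Cda and Gm26992 had the fewest, each with 24 in its lowest library.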

Other observations

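The tests of gene families, of a length bias between single libraries, of the inflammatory genes against matched genes and of the share of endothelial cells were chosen only after the result was seen. Collagens ran against the length trend. Of 8 listed collagen genes, with a median exon length of 8958 bases, 7 rose and Col12a1 fell, with a median fold of 1.18 where matched listed genes had 0.776 (permutation of lists, p = 0.0004, adjusted p = 0.0072 over 18 families). Laminins, the other large matrix family, had 4 listed members that all fell, with a median fold of 0.729 against 0.751 in matched genes (permutation of lists, p = 0.573). Subunits of RNA polymerase II, the enzyme that transcribes messenger RNA, had 8 rises and 1 fall with a median fold of 1.34 against 1.24 (permutation of lists, p = 0.003, adjusted p = 0.027). The fall was that of the large subunit Polr2a, a gene named after its value was seen. Zinc finger genes of the Zfp series had 48 falls and 3 rises, with a median fold of 0.752 against 0.793 (permutation of lists, p = 0.0052, adjusted p = 0.0312).

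In other families nearly all listed members moved one way, and none passed after adjustment against genes matched on length and GC. All 78 listed cytosolic and all 32 mitochondrial ribosomal proteins rose. So did all 34 Nduf genes, mostly subunits of NADH dehydrogenase, and all 11 genes of the Cox4 to Cox8 series of cytochrome c oxidase. All 12 genes of the ATP synthase series Atp5 and all 14 spliceosomal Sm and LSm proteins rose too. Of 23 genes of the series Psma to Psmd, which hold proteasome subunits and Psmc3ip, 22 rose. Mitochondrially encoded subunits are not in these counts, and of the 5 listed, mt-Nd5 fell and the other 4 rose. All 18 listed chromodomain, bromodomain and lysine methyltransferase genes fell, as did all 13 guanine exchange factors of the Arhgef and Dock families, all 9 Arhgap genes and all 8 kinesins, with 16 of 17 Usp genes. Among these the lowest p before adjustment were 0.0122 for the cytosolic ribosomal proteins (median fold 1.28 against 1.25, adjusted p = 0.0549), 0.0158 for the Arhgap genes (median fold 0.677 against 0.763, adjusted p = 0.0569), 0.026 for NADH dehydrogenase (1.29 against 1.25, adjusted p = 0.078) and 0.0488 for mitochondrial ribosomal proteins (1.29 against 1.25, adjusted p = 0.126), all by permutation of lists. Both metallothioneins, Mt1 and Mt2, rose, with a median fold of 1.47 against 1.31 (permutation of lists, p = 0.0934).

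The first pattern is that shorter listed genes were higher and longer ones lower in the chemokine libraries. GC content does not account for it among the listed genes, since the partial rho of fold with length given GC was -0.693. The control pair had a larger gap in sequencing depth than that between the groups. Its change per doubling of length on the log2 scale was 0.00705, against -0.23 between the groups. The genes were selected for a difference between the groups, which can enlarge the second slope against the first. The control pair therefore cannot exclude sequencing depth. A length bias that varies between single libraries remains open, since chemokine 2 over chemokine 1 had a rho of -0.513 with length, though a response that differed in size between these libraries may give the same value. The change per doubling of length within this pair was -0.0481, and over the control mean the chemokine libraries had changes of -0.208 and -0.256. The genes were selected as different between groups that overlap in none of them, which favours a small change within a pair. The smaller change within the pair therefore does not weigh against a length bias. An effect of the chemokines on long and short transcripts is the biological explanation, and it was not tested, because the bias and the treatment coincide in these groups.

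The second pattern is that chemokine, cytokine and acute phase genes were higher, 18 of 21 listed members of the 4 inflammatory lists. Their median fold of 1.25 was close to the 1.23 of random listed genes of the same length and GC classes (permutation of lists, p = 0.327). Those genes were themselves selected as changed, so the group rose like other listed genes of its length and GC content. The comparison cannot say whether length, GC content or the treatment gave the rise. With the trend removed, the log2 fold change of Cxcl1 went from 0.49 ± 0.05 to 0.19 ± 0.06 (adjusted p = 0.0478), that of Ccl2 from 0.56 ± 0.06 to 0.20 ± 0.04 (adjusted p = 0.0112), that of Cxcr2 from 0.42 ± 0.07 to 0.28 ± 0.05 (adjusted p = 0.00619) and that of Saa3 from 0.73 ± 0.05 to 0.53 ± 0.04 (SE, adjusted p = 0.000462), all by limma. Cxcl2 did not pass (0.36 ± 0.05 before and 0.08 ± 0.04 after, adjusted p = 0.185), since the trend took most of its fold. An induction of these genes by the treatment stays open, for the part above the trend and for the part within it.

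The third pattern is the rise of endothelial markers in cells prepared as fibroblasts. It exceeded the change of listed genes matched on length and GC, with p = 0.0004 by permutation of lists. The median fold was 1.42, where the middle 95% of matched lists ran from 0.789 to 1.29. The draws treat the 4 markers as independent genes, though markers of 1 cell type can vary together, and do not measure the spread between libraries. Egfl7 and Ramp2 also share exon bases with other annotated genes, so their reads are uncertain. A larger share of endothelial cells in the chemokine cultures stays open, since that 0 of the 4 listed markers had a fold below 1 is the pattern itself, 11 of the 15 markers were not analysed here and the levels were low, from 1.68 RPKM for Pecam1 to 17.5 RPKM for Ramp2 in control. Fibroblast markers had 6 rises and 1 fall, and the 3 macrophage markers fell but were not told apart from matched genes (permutation of lists, p = 0.329), so changes in the shares of these cells stay open. A response of endothelial cells or fibroblasts to the chemokines was not tested.

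Overlap with other genes was compared for the exceptions to the length trend. Among listed genes of up to 3060 bases, 13 of 35 that fell and 305 of 859 that rose shared exon bases with another annotated gene (Fisher's exact test, p = 0.858). Those lying wholly inside another gene were 4 of the 35 (11.4%) and 51 of the 859 (5.94%), which did not pass either (Fisher's exact test, p = 0.266).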
